A study of Mus musculus with 60 samples.

How the data were processed

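Bulk RNA sequencing measured gene expression in mouse cancer-associated fibroblasts (CAFs) that were grown alone or with mouse lung cancer cells. The 60 libraries came as 3 tables. The aggregate table holds 9 libraries from multicellular aggregates, with 3 replicates each of CAFs alone, CAFs with 393P cells and CAFs with 344SQ cells. The shRNA table holds 6 libraries from aggregates of CAFs with 344SQ cells that carried a control shRNA (shCTL) or an shRNA against Zeb1 (shZEB1), with 3 replicates each. The Boyden table holds 45 libraries from CAFs kept apart from the cancer cells by a membrane, with 5 biological replicates of each of 3 groups and 3 technical libraries per replicate. Per the labels, CAFs were enriched by fluorescence-activated sorting before lysis, and the fragments were made by sonication and ligation.

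The deposited files hold raw counts per gene and library, which the authors made by alignment with STAR and counting with HTSeq on the mouse genome build mm10. Tool versions, the annotation release, the strand setting and any filter are not given in the sources used here. Every table lists 48440 genes, and all values are whole numbers from 0. Identifiers, positions and overlapping genes were taken from the GENCODE M21 annotation of GRCm38, the same assembly as mm10. Because the strand setting is unknown, counts of genes that overlap others on the opposite strand are uncertain, and so are those of genes with close paralogs.

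The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 3 technical libraries of each Boyden replicate were summed, so the unit of replication was the biological replicate. Each table was fitted on its own, with a mean per group. Genes with low counts were removed by filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and 2-sided edgeR quasi-likelihood tests compared the groups. Benjamini-Hochberg adjustment ran over all genes tested in a comparison, and genes with an adjusted p under 0.05 were called changed. Log2 changes are given with their standard errors (SE), and levels as TMM-scaled CPM, the usual depth-normalised read count, with the standard deviation (SD) over replicates. Summed CPM of carcinoma markers, and the summed gains set against them, were scaled by total counts without TMM.

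Gene groups were read from 30 lists with 844 members in all, drawn up from textbook knowledge. Each list with at least 5 genes tested was compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation. Counts of list members called are given over all genes tested and adjusted over the list alone. The rotation test fry was also run. Its p asks whether the genes of a set moved, on balance, in 1 direction, and it compares the set with no other genes.

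The effect of the culture format was tested by fitting the aggregate and Boyden tables jointly and testing the difference between the log2 changes of the formats. Comparisons that share the CAFs-alone libraries have correlated log2 changes, so the shared changes were set against simulated data with no effect of either line, in 50 runs for the aggregates and 20 for the Boyden chamber. Correlations between tables run across genes, which are not independent replicates.

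The text names genes by a rule. For each comparison it took the 8 genes with the largest rise and the 8 with the largest fall among genes called, with replicate values that did not overlap between the groups and a mean of at least 5 CPM in the higher group. It added up to 4 members of each list, those with the smallest p past the threshold, or the 2 of highest level where none passed. It always included Zeb1, Acta2, Il6, Col1a1, Epcam and Cdh1, but Epcam passed the count filter in no table and Cdh1 did not pass it in the aggregates. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

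Most alternatives changed 1 choice at a time. They were no filter, RLE size factors, upper-quartile scaling, DESeq2 1.42.0 in place of edgeR, a fit of only the groups compared, a log2 change of at least 1, a block for the replicate number, the first technical library of each Boyden replicate alone, limma-voom on the 45 Boyden libraries, an estimated correlation or fry for the lists, and each replicate left out in turn. DESeq2 was run on all genes with counts and with its own filtering, so it changed the tool and the filter together, and limma-voom changed the tool, the unit and the genes tested. Added after seeing the data were the removal of rRNA-like and mitochondrial genes before scaling, the other technical library sets alone, 393P Boyden replicate 1 without its technical library 2 (the Boyden library richest in carcinoma markers), Boyden counts thinned to the smallest sum, the marker level of carcinoma cells as a covariate, the removal of libraries rich in those markers, and the lists and joint comparisons without each replicate. Other splits of the samples into groups of the same sizes were fitted in the same way, all 10 for groups of 3 and 100 drawn at random for the rest.

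Recovery was tested on simulated data, with a 2-fold or a 4-fold change put into 100 genes each. Between 46% and 52% of the 2-fold changes and 92% to 96% of the 4-fold changes were called in the aggregates. In the Boyden table the shares were 87% to 91% and 97% to 99%. In the shRNA table they were 0% and 0%. In the joint fits of the formats 21% to 32% of 2-fold and 61% to 63% of 4-fold differences were called. No block for the replicate number was used. After the group means were removed, samples with the same number correlated by -0.0299 to 0.0717 across the aggregate groups, by -0.0299 to 0.126 across the shRNA groups and by -0.303 to 0.265 across the Boyden groups, so the numbers do not pair the samples.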

Results

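The data describe how mouse CAFs, the activated fibroblasts of tumours, changed when grown with cancer cells. The labels call them tCAFs and do not explain the prefix. 393P and 344SQ are mouse lung adenocarcinoma lines; 393P is known as poorly metastatic and 344SQ as metastatic. The aggregate libraries held 757717 to 1258751 counts each, the shRNA libraries 739530 to 2144803, and the sums of the Boyden technical libraries 4182944 to 8542262. Among these sums the 344SQ group was the shallowest, with 4182944 to 5857925 counts, against 6227570 to 7126107 for 393P and 6734110 to 8542262 for CAFs alone. In the aggregates the 10 most abundant genes took 45.3% to 53.3% of the counts and rRNA-like genes 18.7% to 24.6%. In the Boyden sums these shares were 14.8% to 18.4% and 0.0230% to 0.0574%. The biological coefficient of variation was 16.2% in the aggregates, 61.7% in the shRNA table and 8.58% in the Boyden table. Technical libraries of the same Boyden replicate correlated by -0.069, as estimated by limma. They were thus no more alike than libraries of different replicates in a group. The 8.58% may therefore hold variation between libraries, and the part due to biological replicates was not tested. Replicates are described as biological, but nothing says whether they came from separate fibroblast isolates, so errors and p-values describe the spread between these samples.

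The first comparison asked what 393P cells changed in the CAFs they were aggregated with. CAFs with 393P had far higher levels of collagen genes and of the mural cell markers tested, and lower levels of C3 and Cxcl12. Postn, which encodes the matrix protein periostin (ENSMUSG00000027750.16, chromosome 3, 54361109 to 54391037), rose from 32.8 ± 3.47 to 372 ± 37.0 CPM (SD, n = 3 per group), a log2 change of 3.49 ± 0.20 (SE). The basement membrane collagen Col15a1 (ENSMUSG00000028339.17, chromosome 4, 47208161 to 47313167) rose from 59.5 ± 17.8 to 555 ± 26.1 CPM, and the receptor gene Notch3 (ENSMUSG00000038146.7, chromosome 17, 32120820 to 32166852) from 18.0 ± 2.61 to 146 ± 16.6 CPM. The complement gene C3 (ENSMUSG00000024164.15, chromosome 17, 57203970 to 57228136) fell from 1036 ± 121 to 75.4 ± 38.3 CPM. For each of these genes the replicate values of the groups did not overlap.

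Of 17 collagens tested, 12 rose with 393P and 1 fell (12 and 2 adjusted over the list alone). Col5a3 rose by 3.16 ± 0.22 on the log2 scale, Col6a3 by 2.66 ± 0.18 and Col1a1, the main fibrillar collagen, by 0.87 ± 0.17. The collagen list kept its call with an estimated correlation (adjusted p = 2.44e-09 with the preset correlation and 0.0104 with the estimated one), and it was the only list of this comparison that did. All 3 mural cell markers tested rose, Notch3 by 3.00 ± 0.23, Pdgfrb by 2.12 ± 0.17 and Cspg4 by 2.74 ± 0.38, but the list was too short for the list test, and Rgs5, Abcc9, Kcnj8, Higd1b, Myh11 and Des had 0 to 2 counts per aggregate library. Flt1, a vascular endothelial growth factor receptor gene that is on the endothelial list, rose from 46.9 ± 12.5 to 403 ± 101 CPM, and it was 1 of 2 endothelial markers tested. Other matrix genes moved both ways: glycoproteins gave 8 higher and 6 lower of 25 (9 and 9 adjusted over the list alone) and matrix proteases 5 and 6 of 25 (6 and 7 adjusted over the list alone), and neither list was called (adjusted p = 0.788 for each). Fap, the gene of fibroblast activation protein, rose by 3.52 ± 0.29, and the guidance genes Sema7a and Robo1 by 3.75 ± 0.38 and 3.37 ± 0.47.

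Of 16 genes of the inflammatory CAF list, 2 rose and 8 fell (3 and 9 adjusted over the list alone; adjusted p = 0.0785 with an estimated correlation). Those that fell included Cxcl12, a chemokine that draws leukocytes, by a log2 change of -2.73 ± 0.18, Efemp1 by -3.55 ± 0.22 and Pdgfra by -1.86 ± 0.21. Il6 went the other way, from 7.49 ± 3.94 to 27.5 ± 10.7 CPM (log2 change 1.95 ± 0.44). Of 16 Wnt, Notch and Hedgehog targets, 8 rose and 1 fell (10 and 3 adjusted over the list alone; adjusted p = 0.119 with an estimated correlation), among them the Notch target Heyl (4.53 ± 0.44). Of 15 p53 targets 9 fell and none rose (10 and 0 adjusted over the list alone; adjusted p = 0.0803 with an estimated correlation), including the cell cycle inhibitor Cdkn1a (-1.17 ± 0.19) and Ccng1 (-1.17 ± 0.20). Of 25 cholesterol and lipid synthesis genes 11 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 0.152 with an estimated correlation), including Hmgcs1 (1.34 ± 0.28) and their regulator Srebf2 (1.11 ± 0.20). Of 19 regulators of epithelial-mesenchymal transition 9 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.0567 with an estimated correlation), among them Cdh11 (2.27 ± 0.22) and Zeb1 (0.85 ± 0.18). The TGF-beta response list was mixed, with 6 of 25 genes higher and 4 lower (8 and 5 adjusted over the list alone; adjusted p = 0.0492, and 0.212 with an estimated correlation). Tgfb1 rose by 1.94 ± 0.20 and Pmepa1 by 1.31 ± 0.17, while Thbs1 fell by 1.71.

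In all, edgeR called 853 of 7992 genes, 432 higher and 421 lower, with the smallest adjusted p at 4.76e-13 for Postn. Acta2, the smooth muscle actin gene, rose by 1.41 ± 0.43 (adjusted p = 0.0295), but its call was lost without CAFs alone replicate 1 (0.99), CAFs alone replicate 2 (1.16), 393P replicate 2 (1.40) or 393P replicate 3 (0.95). Carcinoma markers summed to 166 CPM in 393P replicate 3 and to 53.4 to 106 CPM in the other aggregate libraries.

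**Figure D1:**
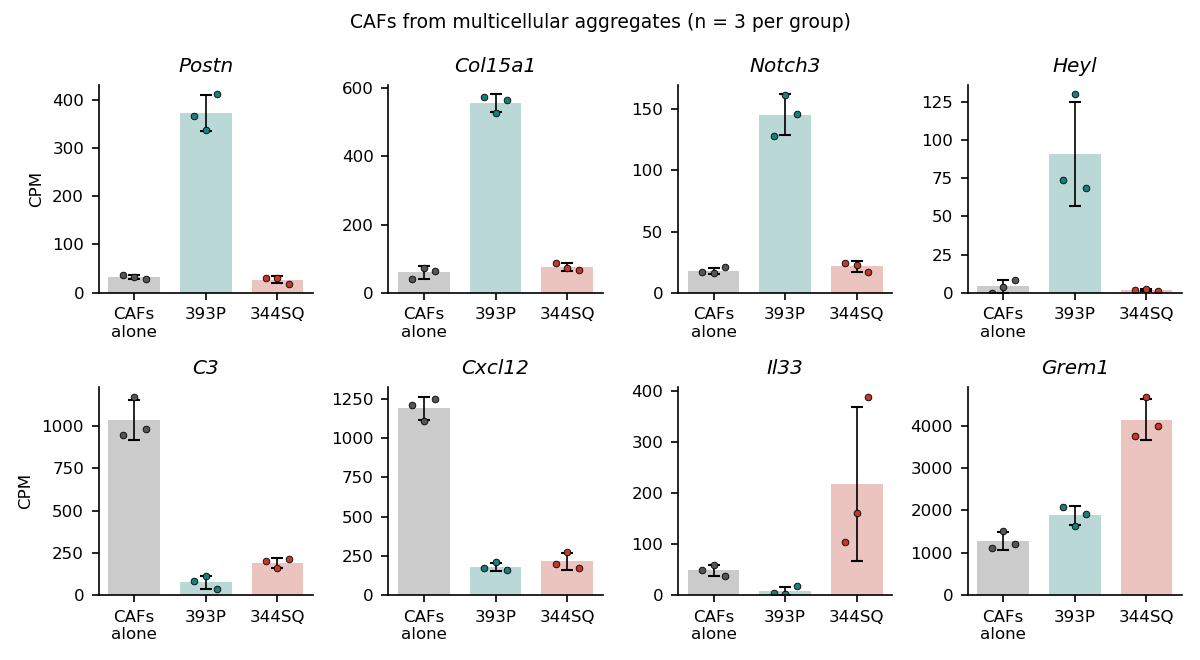
Levels of 8 genes in CAFs from aggregates, in CPM, for CAFs alone, with 393P and with 344SQ. Bars give the mean, error bars the SD and points the 3 replicates, with the SD drawn down to 0 at most; Postn, Col15a1, Notch3 and Heyl were high with 393P, C3 and Cxcl12 were high in CAFs alone, and Il33 and Grem1 were highest with 344SQ.

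The same question was asked of 344SQ cells. C3 and Cxcl12 fell with 344SQ as well, and Grem1 and Ptgs2 were among the genes that rose. Cxcl12 (ENSMUSG00000061353.11, chromosome 6, 117168535 to 117181367) fell from 1191 ± 74.6 to 214 ± 51.3 CPM (SD, n = 3 per group), a log2 change of -2.48 ± 0.17 (SE). The hyaluronidase gene Cemip fell from 181 ± 7.13 to 27.4 ± 12.8 CPM. Grem1, an antagonist of bone morphogenetic proteins (ENSMUSG00000074934.3, chromosome 2, 113746164 to 113758646), rose from 1275 ± 215 to 4146 ± 486 CPM, and Ptgs2, the inducible prostaglandin synthase, from 346 ± 78.7 to 930 ± 216 CPM. Replicate values of the groups did not overlap for any of these 4 genes.

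Of 16 Wnt, Notch and Hedgehog targets 6 rose and none fell (7 and 1 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation). The Wnt pathway genes Axin2, Nkd2 and Sfrp2 rose by 2.09 ± 0.31, 2.78 ± 0.30 and 2.46 ± 0.28. Of 19 regulators of epithelial-mesenchymal transition 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation), and the transcription factor genes Twist1 and Snai1 rose by 2.69 ± 0.37 and 1.16 ± 0.20. Of 25 TGF-beta response genes 4 rose and none fell (5 and 0 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation), among them Pmepa1 (1.10 ± 0.17). Cholesterol and lipid synthesis genes gave 4 higher and 0 lower of 25 (7 and 0 adjusted over the list alone; adjusted p = 0.316 with an estimated correlation), and p53 targets 0 higher and 2 lower of 15 (0 and 3 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation). None of these lists kept its call with an estimated correlation. Of 24 chemokine and growth factor genes 6 rose and 2 fell (8 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.0796, and 0.508 with an estimated correlation). The growth factor gene Ereg rose by 2.40 ± 0.25, the opioid precursor Penk by 3.41 ± 0.42 and osteopontin (Spp1) by 2.25 ± 0.19, while C3 fell by 2.43 and Efemp1 by 1.80. In the matrix, Tnc, Fbn1 and Serpine2 rose by 1.71 ± 0.30, 1.09 ± 0.15 and 2.53 ± 0.29, and Tnxb and Fbln2 fell by 2.30 and 1.08.

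In all, edgeR called 467 of 7992 genes, 278 higher and 189 lower, with an adjusted p of 1.33e-10 for Cxcl12, and without CAFs alone replicate 3 it called 284, 160 higher and 124 lower. Col1a1 had a log2 change of -0.04 ± 0.17 (adjusted p = 0.949), Zeb1 of 0.24 ± 0.18 (adjusted p = 0.579) and Acta2 of -0.64 ± 0.52 (adjusted p = 0.611), the last turning to 0.39 without CAFs alone replicate 3.

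Setting the lines against each other asked which CAF genes depended on the cancer cell. Collagen genes were lower with 344SQ than with 393P: of 17 tested, 11 were lower and 0 higher (13 and 1 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.00286). Col15a1 stood at 75.9 ± 10.7 against 555 ± 26.1 CPM (SD, n = 3 per group), Col6a3 at 634 ± 172 against 2916 ± 98.0 CPM, and Postn at 27.0 ± 7.24 against 372 ± 37.0 CPM (log2 difference -3.79 ± 0.20). Heyl and Notch3 were also lower, by log2 differences of -5.62 ± 0.50 and -2.76 ± 0.22, and so was the Notch ligand Jag1 (-1.52 ± 0.24). Higher with 344SQ was the alarmin Il33 (ENSMUSG00000024810.16, chromosome 19, 29925114 to 29960718), at 218 ± 151 against 8.28 ± 8.29 CPM, with 389 CPM in 344SQ replicate 3 and 104 CPM in replicate 1.

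Of 16 inflammatory CAF genes 6 were higher with 344SQ and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). C3 was higher by 1.32 ± 0.24, Ptgs2 by 1.07 ± 0.19 and Pdgfra by 1.12 ± 0.22. Il6 was lower (-1.82 ± 0.43), a call lost without 344SQ replicate 3 (-1.46) or 393P replicate 1 (-1.58). Of 24 chemokine and growth factor genes 9 were higher and 1 lower (10 and 3 adjusted over the list alone; adjusted p = 0.267 with an estimated correlation), among them Grem1 (1.14 ± 0.16) and Ereg. Of 20 NF-kB targets 3 were higher and 1 lower, with the same counts adjusted over the list alone (adjusted p = 0.342 with an estimated correlation), and Csf1 was higher by 1.36 ± 0.22. Immediate early genes, which respond to signals and to handling of cells, gave 6 higher and 2 lower of 29 (9 and 3 adjusted over the list alone; adjusted p = 0.388 with an estimated correlation), with Fosb at 0.99 ± 0.19. Of 15 p53 targets 1 was higher (5 adjusted over the list alone; adjusted p = 0.341 with an estimated correlation). Of 21 collagen processing genes 1 was higher and 3 lower (2 and 3 adjusted over the list alone; adjusted p = 0.267 with an estimated correlation), the latter including Adamts2 (-1.49 ± 0.18) and Loxl3 (-1.03 ± 0.24). In all, edgeR called 332 genes, 177 higher and 155 lower, with an adjusted p of 1.16e-13 for Postn. The lists called numbered 7, and 3 without 393P replicate 2.

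Both lines also changed CAFs in a shared way. With 344SQ and with 393P, 299 genes were called in the same direction against CAFs alone and 2 in opposite directions; of the shared genes 155 were higher and 144 lower. Spp1 (2.25 and 2.33), Thy1 (2.06 and 2.08) and Pmepa1 were among the higher, and C3, Cxcl12 and Efemp1 among the lower. The comparisons share their control libraries, which alone makes their log2 changes correlate. Simulated data with that sharing and no effect of either line gave a correlation of 0.51 between the log2 changes across genes, against 0.66 measured. The simulated covariance was 0.0588, against 0.237, and 0 genes were called the same way in every run. With no effect simulated hardly any gene is called, so that 0 does not show what sharing adds when each line has effects of its own. Without CAFs alone replicate 3 the shared genes numbered 185.

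The shRNA table asked what loss of Zeb1, a repressor of epithelial genes, in 344SQ cells changed in the CAFs around them. Zeb1 itself stood at 71.8, 105 and 50.3 CPM in the shCTL libraries and at 144, 48.4 and 120 CPM in the shZEB1 libraries, a log2 change of 0.47 ± 0.53 (SE, n = 3 per group, adjusted p = 0.896). The knockdown was in the cancer cells, which sorting depletes, so these levels do not test it. The gene of lipocalin 2, Lcn2, stood at 3.95 to 17.9 CPM with shZEB1 and at 65.6 to 297 CPM with shCTL (log2 change -3.92 ± 0.72, adjusted p = 0.384). The collagenase Mmp13 stood at 4.39 to 66.0 against 209 to 1122 CPM (-4.70 ± 0.96, adjusted p = 0.565), and Cemip at 118 to 235 against 20.5 to 25.1 CPM (2.76 ± 0.52, adjusted p = 0.384). Lcn2, Mmp13 and Cemip were chosen after their values were seen, and with 3 samples against 3, chance alone separates the groups of 10% of genes. Acta2 stood at 284 ± 107 against 66.6 ± 11.6 CPM (SD), a log2 change of 2.09 ± 0.46 (adjusted p = 0.666). The acute phase gene Saa3 stood at 30.0 ± 26.8 against 514 ± 560 CPM (-4.05 ± 0.98, adjusted p = 0.686). Its level was 387 and 1126 CPM in shCTL replicates 1 and 2. In shCTL replicate 3 it was 28.05 CPM, within the 8.80 to 60.1 CPM of the shZEB1 libraries.

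No gene passed the edgeR quasi-likelihood test in this table: 0 of 7801 were called and 466 had an unadjusted p under 0.05. DESeq2, run without the count filter, called 26 genes, including Lcn2 (adjusted p = 0.000396), Mmp13 (0.000396), Cemip (0.00224), Saa3 (0.0124) and Acta2 (0.0375). The libraries varied so much that none of the simulated 4-fold changes was recovered. Of 22 NF-kB targets 0 passed (0 higher and 1 lower adjusted over the list alone), with a median log2 change of -0.84. Ptgs2, for example, stood at 652 ± 452 against 1708 ± 338 CPM, while Csf1 went the other way, at 688 ± 187 against 321 ± 229 CPM. Of 19 myofibroblast genes 0 passed (3 higher and 0 lower adjusted over the list alone), with Thbs1 and Sparc at log2 changes of 0.59 ± 0.46 and 0.80 ± 0.46. Camera called both lists with the preset correlation (adjusted p = 0.000708 and 0.0455), and neither with the estimated correlation (adjusted p = 0.781 for both) or with fry (adjusted p = 0.753 for both). Without shCTL replicate 1 the number of lists called was 1, and without shCTL replicate 3 it was 8. Carcinoma markers summed to 340, 254 and 2127 CPM in the shCTL libraries and to 281, 1765 and 1024 CPM in the shZEB1 libraries, so they varied far more within each group than in the other tables. Mitochondrial genes took 40.8% and 36.3% of the counts in shCTL replicates 1 and 2 and 23.5% to 27.6% in the other 4 libraries, and Xist, a transcript of female cells, had 18 counts in each of these replicates and 0 to 2 in the others. The epithelial cadherin Cdh1 followed the carcinoma markers, with 726 CPM in shCTL replicate 3 and 578 CPM in shZEB1 replicate 2.

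**Figure D2:**
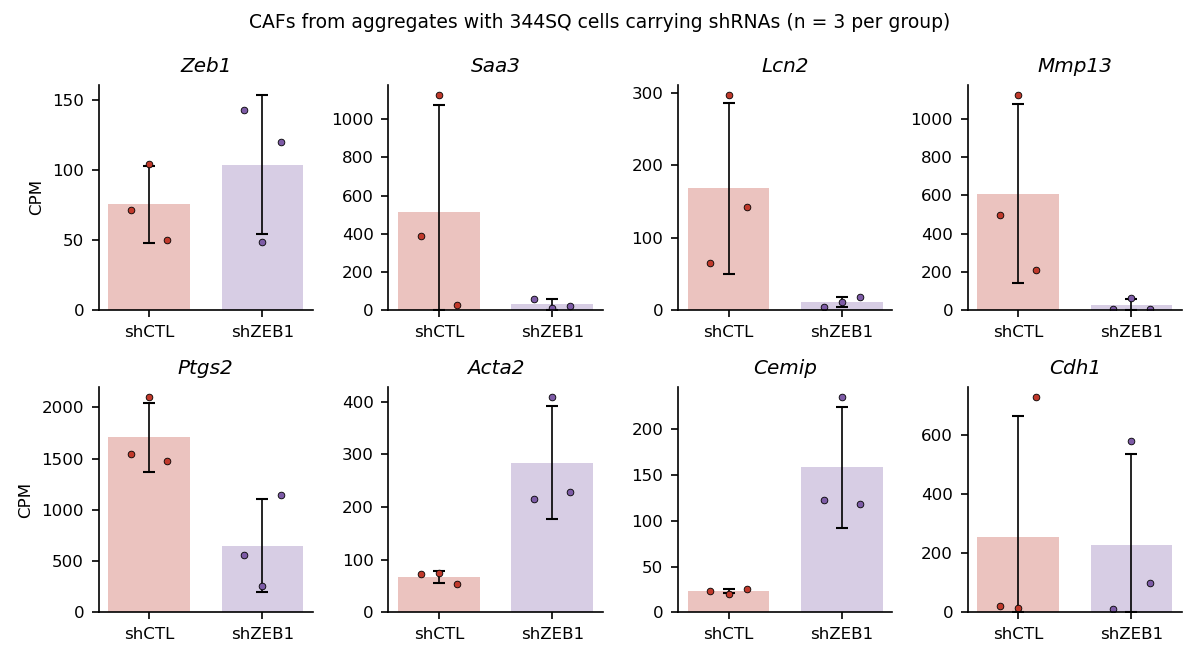
Levels of 8 genes, in CPM, in CAFs from aggregates with 344SQ cells that carried shCTL or shZEB1. Bars give the mean, error bars the SD and points the 3 replicates, with the SD drawn down to 0 at most. Lcn2, Mmp13, Ptgs2, Acta2 and Cemip separate the groups, no gene passed the edgeR test, and Cdh1 is high in single libraries of both groups.

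In the Boyden chamber a membrane stood between the CAFs and the cancer cells, and what crossed it was not measured. Here 344SQ cells raised Saa3, chemokine genes and the proteases Mmp3 and Mmp13 in CAFs. Saa3 (ENSMUSG00000040026.8, chromosome 7, 46711998 to 46715700) rose from 54.7 ± 12.1 CPM in CAFs alone to 2182 ± 259 CPM (SD, n = 5 per group), a log2 change of 5.32 ± 0.13 (SE). The neutrophil chemokine Cxcl5 (ENSMUSG00000029371.7, chromosome 5, 90759360 to 90761624) rose from 0.530 ± 0.226 to 31.9 ± 8.41 CPM, Cxcl1 from 11.5 ± 1.83 to 153 ± 30.0 CPM, and Mmp13 (ENSMUSG00000050578.9, chromosome 9, 7272514 to 7283331) from 4.49 ± 0.757 to 41.9 ± 2.78 CPM. Col3a1, a fibrillar collagen (ENSMUSG00000026043.18, chromosome 1, 45311538 to 45349706), fell from 1071 ± 97.5 to 576 ± 63.7 CPM. The replicate values of the groups did not overlap for these 5 genes. Saa3 and the Cxcl genes have close paralogs, so their counts carry that uncertainty. Cdh1, an epithelial marker, stood at 8.56 ± 5.05 against 2.83 ± 1.06 CPM, a log2 change of 1.54 ± 0.54 (adjusted p = 0.057).

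Of 26 NF-kB targets 20 rose and 0 fell (21 and 0 adjusted over the list alone; adjusted p = 0.000195 with an estimated correlation). Of 22 inflammatory CAF genes 13 rose and 5 fell (14 and 5 adjusted over the list alone; adjusted p = 0.000608 with an estimated correlation), among them Ccl7 (1.61 ± 0.07) and Il6 (1.26 ± 0.10). Of 34 chemokine and growth factor genes 17 rose and 6 fell (23 and 8 adjusted over the list alone; adjusted p = 0.00214 with an estimated correlation), with Cxcl16 at 1.91 ± 0.08. Hypoxia genes rose as a group, 27 higher and 1 lower of 38 (30 and 1 adjusted over the list alone; adjusted p = 3.66e-05 with an estimated correlation), among them the peptide hormone gene Adm (1.24 ± 0.08) and the glycolysis genes Pgk1 (0.93 ± 0.06) and Pdk1 (1.21 ± 0.09).

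Myofibroblast genes and collagens were lower as lists with the preset correlation. Of 22 myofibroblast genes 15 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 0.0583 with an estimated correlation), including Fhl1 (-0.77 ± 0.08) and Sparc (-0.43 ± 0.06), with Igfbp7 higher (0.59 ± 0.08). Acta2 fell from 4086 ± 407 to 2864 ± 637 CPM. Of 20 collagens 10 fell and 0 rose (11 and 1 adjusted over the list alone; adjusted p = 0.0677 with an estimated correlation), and the protease inhibitors Timp3 and Timp2 fell by 0.86 and 0.59, while the proteases Mmp3 and Mmp13 rose by 2.59 ± 0.13 and 3.22 ± 0.12. Glycoproteins (5 higher and 9 lower of 29; 5 and 13 adjusted over the list alone; adjusted p = 0.162), collagen processing genes (3 and 8 of 21; 3 and 11 adjusted over the list alone; adjusted p = 0.0746) and matrix proteases and inhibitors (6 and 9 of 26; 8 and 11 adjusted over the list alone; adjusted p = 0.761) were not called as lists. Of 28 YAP and SRF targets 3 rose and 9 fell (3 and 11 adjusted over the list alone; adjusted p = 0.224 with an estimated correlation), with Vcl at -0.52 ± 0.05. Of 32 stress response genes of the unfolded protein and integrated stress pathways 12 fell and 0 rose (14 and 1 adjusted over the list alone; adjusted p = 0.0583 with an estimated correlation), with Chac1 at -0.74 ± 0.10. Of 42 cell cycle genes 13 rose and 0 fell (18 and 0 adjusted over the list alone; adjusted p = 0.201 with an estimated correlation), with Kif23 at 0.45 ± 0.08 and Cenpf at 0.43 ± 0.07. Axon guidance genes (3 higher and 10 lower of 37; 3 and 11 adjusted over the list alone; adjusted p = 0.0808 with an estimated correlation) and Wnt, Notch and Hedgehog targets (3 and 6 of 14; 3 and 8 adjusted over the list alone; adjusted p = 0.0557 with an estimated correlation) were also lower as lists with the preset correlation. In all, edgeR called 2087 of 14040 genes, 1043 higher and 1044 lower, with an adjusted p of 2.46e-20 for Saa3, and 157 rose and 58 fell by at least 2-fold.

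**Figure D3:**
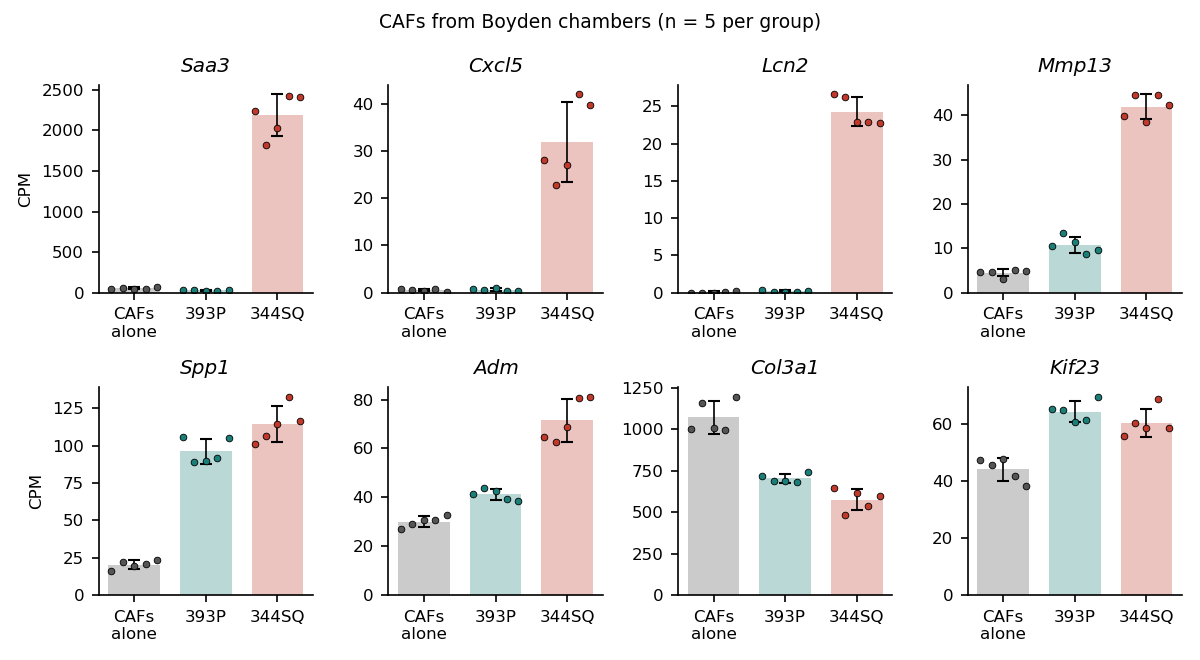
Levels of 8 genes, in CPM, in CAFs from Boyden chambers for CAFs alone, with 393P and with 344SQ. Bars give the mean, error bars the SD and points the 5 biological replicates; Saa3, Cxcl5 and Lcn2 were high with 344SQ, Spp1 was high with both lines, and Col3a1 was lower with both lines.

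Across the membrane 393P cells changed many CAF genes, few of them by 2-fold or more. Spp1 (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050) rose from 20.4 ± 2.98 to 96.4 ± 8.34 CPM (SD, n = 5 per group), a log2 change of 2.24 ± 0.09 (SE), and the proteases Mmp3 and Mmp13 rose by 1.67 ± 0.13 and 1.25 ± 0.14. C3 fell from 1015 ± 150 CPM by a log2 change of -0.64 ± 0.09, Acta2 from 4086 ± 407 to 2632 ± 161 CPM, and Tnc from 181 ± 9.73 to 99.1 ± 12.2 CPM. Saa3 fell by 0.74, and Il6 had a log2 change of -0.04 ± 0.11 (adjusted p = 0.87). Carcinoma markers summed to 226 CPM in 393P replicate 1 and to 129 to 169 CPM in the other 393P sums. Technical library 2 of replicate 1 had 296 CPM of them, the most of any Boyden library. Without that library edgeR called 2309 genes against CAFs alone and 573 between the lines. Cdh1 had a log2 change of 1.12 ± 0.54 (adjusted p = 0.168), and of 0.371 without that library.

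Cell cycle genes rose: 28 of 42 were higher and 0 lower (33 and 0 adjusted over the list alone; adjusted p = 0.0489 with an estimated correlation), with Bub1b, Kif23 and Mcm6 at 0.61 ± 0.09, 0.54 ± 0.07 and 0.48 ± 0.06. Collagens fell, 11 lower and 1 higher of 20 (12 and 1 adjusted over the list alone; adjusted p = 0.0489 with an estimated correlation), with Col3a1 at -0.61 ± 0.07, Col6a1 at -0.53 ± 0.07 and Col1a1 at -0.43 ± 0.06. Hypoxia genes gave 14 higher and 1 lower of 38 (22 and 1 adjusted over the list alone; adjusted p = 0.00949 with an estimated correlation), with Bnip3 at 1.11 ± 0.13 and Pdk1 at 0.75 ± 0.09. Of 22 myofibroblast genes 13 fell and 0 rose (14 and 1 adjusted over the list alone; adjusted p = 0.0549 with an estimated correlation), and of 28 YAP and SRF targets 12 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 0.0549 with an estimated correlation), with Cyr61 at -0.38 ± 0.05. Of 32 cholesterol and lipid synthesis genes 13 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 0.0585 with an estimated correlation), with Scd1 at 0.53 ± 0.06. Of 39 ribosomal protein genes 15 rose and 0 fell (18 and 0 adjusted over the list alone; adjusted p = 0.437 with an estimated correlation), with Rps20 at 0.44 ± 0.09. Of 25 interferon genes 0 rose and 4 fell (0 and 10 adjusted over the list alone; adjusted p = 0.456 with an estimated correlation). Of 26 NF-kB targets 3 rose and 2 fell, and the list was not called (adjusted p = 0.886). A further 7 lists were called with the preset correlation, and with an estimated one their adjusted p lay between 0.129 and 0.515. In all, edgeR called 2195 genes, 1078 higher and 1117 lower, with an adjusted p of 1.79e-14 for Spp1, and only 40 rose and 44 fell by at least 2-fold.

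Compared directly in the Boyden chamber, 344SQ against 393P set apart an inflammatory and hypoxia response. Saa3 was higher by a log2 difference of 6.05 ± 0.13 (SE, n = 5 per group), at 2182 ± 259 against 32.8 ± 5.13 CPM (SD). Lcn2 (ENSMUSG00000026822.14, chromosome 2, 32384633 to 32388252) stood at 24.3 ± 1.93 against 0.236 ± 0.118 CPM, Cxcl1 was higher by 3.62 ± 0.12 and Il6 by 1.29 ± 0.11. Of 26 NF-kB targets 17 were higher and 0 lower (23 and 0 adjusted over the list alone), of 22 inflammatory CAF genes 11 and 1 (13 and 2 adjusted over the list alone), of 38 hypoxia genes 22 and 0 (31 and 1 adjusted over the list alone), and of 34 chemokine and growth factor genes 12 and 4 (14 and 4 adjusted over the list alone). With an estimated correlation the adjusted p was 1.72e-05 for each of the first 3 of these lists and 0.000488 for the chemokine and growth factor list. Bnip3 was higher by 0.96 ± 0.11, Ccl7 by 1.75 ± 0.07 and Tnc by 0.97 ± 0.09. Of 27 TGF-beta response genes 6 were higher and 2 lower (8 and 3 adjusted over the list alone; adjusted p = 0.0728 with an estimated correlation). A further 9 lists were called with the preset correlation, and with an estimated one their adjusted p lay between 0.0728 and 0.6. Col1a1 differed by 0.17 ± 0.06 (adjusted p = 0.114), Zeb1 by 0.14 ± 0.06 (adjusted p = 0.223) and Cdh1 by 0.41 ± 0.49 (adjusted p = 0.756). In all, edgeR called 545 genes, 354 higher and 191 lower, with an adjusted p of 3.73e-21 for Saa3. Without 344SQ replicate 4 it called 759 genes, 51.6% of them higher and 367 lower, and the lower genes numbered 127 without 393P replicate 4 and 113 without 393P replicate 5.

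Against CAFs alone, 1085 genes were called in the same direction with 344SQ and 393P in the Boyden chamber, 459 higher and 626 lower, and 16 in opposite directions. Spp1, Mmp3, Bnip3, Pdgfra and Kif23 were higher with both lines and Col3a1, Vcl and Acta2 lower. The log2 changes correlated by 0.629 across genes, against 0.451 in simulated data that shared controls without an effect of either line. There 0 genes were called the same way in every run, which the lack of any simulated effect makes nearly certain. When the CAFs-alone replicates were divided between the comparisons, 450 genes were called in the same direction and the correlation was 0.405.

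The culture formats were then compared, asking whether cancer cells changed CAFs alike in contact and across a membrane. Collagens went opposite ways with 393P. Of 20 tested, 13 had a higher change in aggregates and 1 a lower one (adjusted p = 2.02e-05 with an estimated correlation), with a median log2 change of 1.27 in aggregates and -0.28 in the Boyden chamber. The difference between the changes was 1.37 ± 0.15 (SE) for Col1a1 and 2.94 ± 0.30 for Tnc. It was -3.02 ± 0.22 for C3 and -2.55 ± 0.20 for Pdgfra, which fell with 393P in aggregates and rose in the Boyden chamber. For Il6 it was 2.10 ± 0.39. Joint edgeR fits over 15193 genes called 1365 genes with different effects of 393P between the formats, 719 with different effects of 344SQ and 511 with different gaps between the lines. These fits shared 1 spread between the formats, with a biological coefficient of variation of 9.5%, against 16.2% in the aggregates fitted alone. For Col1a1 with 393P the SE was larger in the aggregates alone than for the difference. The SEs and p-values of the differences are thus likely too small, and the counts too high. With 344SQ, 2 of 27 inflammatory CAF genes had a higher and 11 a lower change in aggregates than in the Boyden chamber (median difference -1.02, adjusted p = 0.000407 with an estimated correlation); in aggregates 2 of 16 rose and 6 fell (3 and 7 adjusted over the list alone), against 13 and 5 of 22 in the Boyden chamber. Of 21 Wnt, Notch and Hedgehog targets 6 had a higher and 0 a lower change in aggregates (median difference 0.91, adjusted p = 0.000305 with an estimated correlation), with a median log2 change of 0.65 in aggregates and -0.25 in the Boyden chamber.

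Spp1 did not pass the test of a difference between formats, with differences of -0.19 for 344SQ (adjusted p = 0.702) and 0.16 for 393P (adjusted p = 0.729). Across 7827 genes the log2 differences between 344SQ and 393P in aggregates and in the Boyden chamber correlated by 0.0393 (Pearson; Spearman 0.0292), and across 6903 genes those in aggregates correlated with shCTL against shZEB1 by 0.0620 (Pearson; Spearman 0.0551). Each format is a table of its own with its own depth and rRNA share, so the format cannot be told apart from the experiment.

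**Figure D4:**
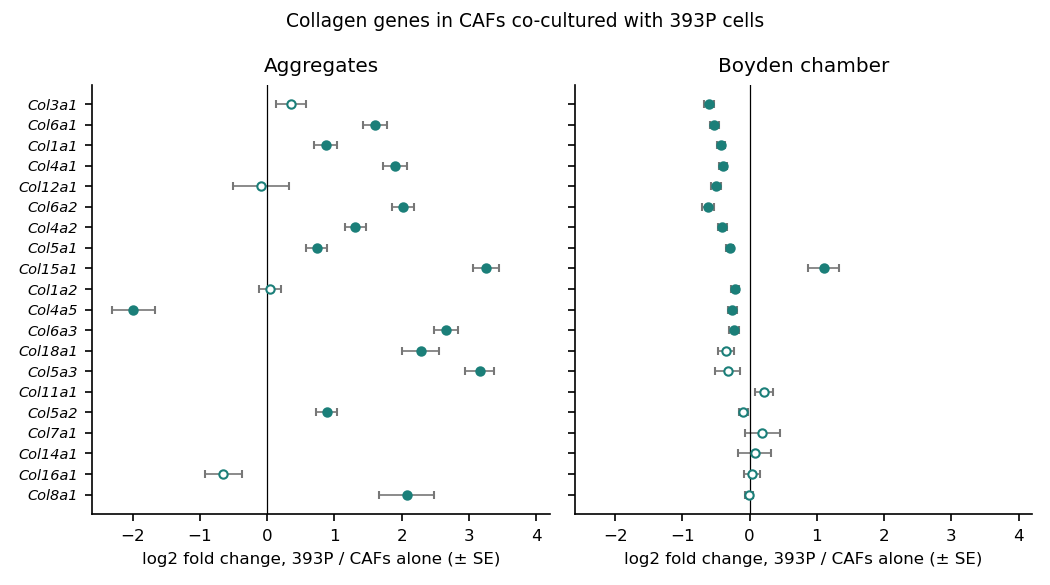
Log2 change of collagen genes with 393P against CAFs alone, in aggregates and in the Boyden chamber, with SE as error bars and filled points for an adjusted p under 0.05. In aggregates 12 collagens were called higher and in the Boyden chamber 11 were called lower.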

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

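Chosen after the results were seen were the tests of carcinoma cell RNA in the aggregates and in the Boyden chamber (by summed markers, and without the 393P library richest in them), of separate experiments, and of technical libraries by size of change; the others were set before.

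Among the genes named in the Boyden chamber, 8 of 130 gene and group pairs had 1 replicate of 5 that stood apart from the rest, and chance alone gives about 1 in 20. These were Bub1b in 393P replicate 5 (33.8 CPM against 28.2 to 28.8), Cyr61 in CAFs alone replicate 4 (751 against 705 to 717), Ltbp2 in 393P replicate 3 (191 against 157 to 166), Mmp13 in CAFs alone replicate 3 (3.19 against 4.62 to 5.13), Rpl7 in CAFs alone replicate 1 (522 against 476 to 484), Scd2 in 393P replicate 5 (598 against 528 to 544), Slc7a5 in 344SQ replicate 2 (154 against 110 to 119) and Steap4 in CAFs alone replicate 5 (4.87 against 2.83 to 3.26).

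Effects differed between aggregates and the Boyden chamber by the test of the difference itself. With 344SQ against CAFs alone 719 genes differed (396 with a higher change in aggregates and 323 with a lower one), with 393P against CAFs alone 1365 (809 and 556), and between 344SQ and 393P 511 (213 and 298). In each case 1 of 100 splits of the samples, the real one, gave as many, and the highest other gave 509, 1064 and 422. A random division of the samples was thus excluded for each count. The splits relabelled samples within each format and could keep the real groups of 1 format, so they do not test whether effects differ between formats. The joint fits also shared 1 spread between the formats, which likely makes the counts too high. With 344SQ the inflammatory CAF list differed by a median of -1.02 and the Wnt, Notch and Hedgehog targets by 0.905. With 393P the median differences were -0.802 for the inflammatory CAF list, 1.58 for collagens, 0.609 for the TGF-beta response, -0.726 for p53 targets, 0.574 for regulators of epithelial-mesenchymal transition and 1.46 for Wnt, Notch and Hedgehog targets. Among genes, 393P gave differences of 2.12 for Acta2, -3.02 for C3, 1.37 for Col1a1, 2.10 for Il6, -2.55 for Pdgfra, 2.94 for Tnc and 0.88 for Zeb1. Between 344SQ and 393P the differences were -2.21 for Acta2, -1.11 for Col1a1, -3.18 for Il6 and -0.79 for Zeb1, and collagens had a median difference of -1.38.

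In the aggregates, groups of 3 allow only 10 splits, too few to exclude chance. There 1 of 10 splits gave as many genes as each real comparison, with real counts of 467, 853 and 332 and 0 as the highest other in each. For the lists, 3 of 10 splits reached the 5 called with 344SQ (highest other 6), 1 of 10 the 7 with 393P (highest other 5) and 1 of 10 the 7 between the lines (highest other 6). In the shRNA table all 10 splits reached the real count of 0 genes, and the highest other called 38. That split set shCTL replicate 3, shZEB1 replicate 2 and shZEB1 replicate 3, the 3 libraries richest in carcinoma markers, against the rest, which points to that structure of the samples. For its lists 6 of 10 splits reached the real count of 2, with 12 as the highest other. In the Boyden chamber chance was excluded for the gene counts, since 1 of 100 splits, the real one, reached 2087, 2195 and 545 genes. The highest others gave 1644, 325 and 116, and the split with 1644 swapped 344SQ replicate 2 with CAFs alone replicate 2. Without 344SQ replicate 2 the 2087 genes became 2774. After the group means were removed, CAFs alone replicate 1 correlated by 0.414 with 344SQ replicate 2 and by -0.366 with 344SQ replicate 3. The samples thus hold structure that cuts across these groups, and its cause was not tested. Chance was excluded for the lists called with 393P (2 of 100 splits reached 15, highest other 15) and between the lines (1 of 100 reached 14, highest other 12), but not for those with 344SQ, where 12 of 100 splits reached 11 and the highest other gave 14. For genes called the same way with both lines, 1 of 100 splits, the real one, reached 299 in aggregates (highest other 105). In the Boyden chamber 1 of 100 reached 1085 (highest other 104). A random division of the samples was thus excluded for both counts. These splits shuffled the samples over all 3 groups, which mixes the effect of each line into every group. They therefore do not test whether the lines share a response beyond their shared controls. Chance was not excluded for the correlations across genes. There 10 of 100 splits reached 0.062 between aggregates and the shRNA table (highest other 0.108). Between aggregates and the Boyden chamber 32 of 100 reached 0.0393 (highest other 0.129).

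The median log2 change of NF-kB targets in CAFs with shZEB1 cells was -0.841, with 16 of 22 members lower and 6 higher, although no gene passed. A share of carcinoma cells that the markers follow alike in both groups is argued against as the whole cause, since with the marker level as a covariate the median was -0.768. The test assumes the same marker level per carcinoma cell with shCTL and shZEB1. Zeb1 represses epithelial genes, so the knockdown may change that level, and carcinoma cells left in some libraries stay open. A single library is argued against as well, because the median nearest 0 without any 1 library was -0.68, without shZEB1 replicate 2. A lower NF-kB response of CAFs to cells with less Zeb1 may remain, as a hypothesis, but the list lost its call with an estimated correlation and other differences between the 6 cultures stay open, among them RNA quality and the make-up of the cells, since shCTL replicates 1 and 2 stood apart in mitochondrial share (40.8% and 36.3% against 23.5% to 27.6%) and in Xist (18 counts each against 0 to 2).

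Collagens rose with 393P in aggregates and fell with it in the Boyden chamber. Carcinoma markers gained 21.2 CPM where the collagens gained 9434 CPM, or 0.224%, which decided nothing because no library holds carcinoma cells alone; their RNA in 393P replicate 3, the library richest in these markers, is argued against as the whole cause, since 12 of 12 collagens were still called higher without it. The rRNA-like and mitochondrial counts are argued against as well, since 12 of 12 collagens were still called higher without these genes. Separate experiments cannot be told apart from the culture format, because each format has 1 table. In 393P replicates 1 and 2 the markers summed to 53.43 and 64.35 CPM, below the 70.45 to 75.23 CPM of CAFs alone. This argues against carcinoma cells rich in these markers in those libraries. A response of CAFs to contact with 393P cells could account for the pattern, as a hypothesis. So could any other difference between the experiments or RNA of carcinoma cells low in these markers.

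NF-kB targets rose with 344SQ in the Boyden chamber. Lower depth of the 344SQ sums is argued against, since 20 of 20 members were still called higher after thinning. Carcinoma markers changed by -0.863% of the gain of the list, which decided nothing because no library holds carcinoma cells alone and the markers stood at 175 CPM in CAFs alone. In the technical library sets alone at least 10 of 20 members were called, on the bound set for that test. By size of change the rise was not confined to 1 set, since the lowest median log2 change in any set was 0.955 against 1.06 in the sums. The members were chosen on the sums of these same libraries, which favours a rise in each set, so differences between technical libraries stay open. A response of CAFs to factors secreted by 344SQ cells may account for the pattern, as a hypothesis found and tested on the same data, and carcinoma cells in the CAF compartment stay open.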

How the results depend on the processing

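Alternatives chosen after seeing the data were the removal of rRNA-like and mitochondrial genes, thinning, technical libraries 2 and 3 alone, 393P Boyden replicate 1 less its technical library 2, the carcinoma marker covariate, the removal of the libraries richest in those markers, and the lists, joint fits and correlations without each replicate.

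Of 202 results for named genes, 177 were past the threshold, and 134 of these stayed past it with the same sign under every alternative run. Another setting took 60 values of 37 results back over the threshold and 18 values of 8 results past it, out of 3483 alternative values in all, and leaving out a replicate did so for 55 values of 17 results and for 2 values of 2 results. With DESeq2, which also replaced the filter by its own, the counts of genes were 343, 638 and 257 in aggregates and 2017, 2125 and 616 in the Boyden chamber. With a block for the replicate number they were 467, 870 and 321 in aggregates, 1 in the shRNA table, 1767, 1796 and 426 in the Boyden chamber, 664, 1276 and 457 for the differences between formats, and 307 and 895 for genes called the same way; lists called with the block numbered 5, 6, 6, 1, 11, 15 and 14.

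A log2 change of at least 1 left 292, 559 and 203 genes in aggregates and 215, 84 and 78 in the Boyden chamber, by construction fewer. Single technical libraries, with fewer counts, gave 500, 513 and 739 genes for 344SQ against CAFs alone, 609, 199 and 1133 for 393P against CAFs alone, and 73, 280 and 152 between the lines. Leaving out 1 replicate gave 284 to 421 genes for 344SQ against CAFs alone in aggregates, lowest without CAFs alone replicate 3, and 185 to 300 genes called the same way in aggregates, lowest without the same library. Fewer samples lower such counts, and why this library mattered most was not tested.

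In the shRNA table the count of 0 genes became 90 without the filter, 26 with DESeq2 run without that filter, 1 with the block and 1 without the library of each group richest in carcinoma markers; the cause was not tested. Its count of 2 lists became 0 with an estimated correlation, 0 with fry, 1 with the block, 5 without the richest libraries, and 1 (without shCTL replicate 1) to 8 (without shCTL replicate 3) when a replicate was left out. With an estimated correlation the lists called numbered 0, 1 and 1 in aggregates and 4, 3 and 4 in the Boyden chamber. Between the lines in aggregates fry called 3 lists, and leaving out a replicate gave 3 (without 393P replicate 2) to 7. The cause was not tested.

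The correlation of the aggregates with the shRNA table ranged from 0.0336 (without shCTL replicate 2) to 0.0904 (without shCTL replicate 3) and was 0.0957 without the richest libraries, and that of aggregates with the Boyden chamber ranged from 0.0163 to 0.0624, without 393P aggregate replicates 2 and 1. The cause was not tested.

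Signs turned for genes that had not passed, and for Cenpa, which had. In aggregates with 344SQ, leaving out a replicate gave -1.41 to 0.39 for Acta2, -0.20 to 0.55 for Il6 and -0.18 to 0.11 for Col1a1. In the shRNA table Cdh1 ranged from -2.14 to 3.62 and was 1.58 without the richest libraries. In the Boyden chamber with 393P, Il6 was 0.082 and 0.294 in technical libraries 1 and 3, 0.204 after thinning, 0.025 without 1 technical library of 393P replicate 1, and -0.110 to 0.042 when a replicate was left out; Zeb1 was -0.076 in technical library 2 and -0.001 to 0.06 when a replicate was left out, and Cdh1 was -0.738 in technical library 1. Between the lines Acta2 was -0.041 in technical library 1 and -0.017 to 0.180 when a replicate was left out, and Cenpa was 0.083 in technical library 1. The cause was not tested. The count filter kept 7992 genes in the aggregates, against 14040 in the Boyden chamber, which limits the aggregate comparisons. Depth, group size and rRNA-like share differed between these formats, and their parts in this were not tested.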

Other observations

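The test of the Boyden genes in the shRNA table was chosen after the results were seen.

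Osteopontin rose in CAFs in every co-culture with an unmodified line: Spp1 had log2 changes of 2.25 and 2.33 with 344SQ and 393P in aggregates and of 2.48 and 2.24 in the Boyden chamber. Pdgfra, a receptor of resting and inflammatory fibroblasts, rose in the Boyden chamber by 0.86 ± 0.05 (SE) with 344SQ and 0.75 ± 0.05 with 393P. Figf, which encodes vascular endothelial growth factor D, fell by 0.90 with 393P in the Boyden chamber, from 557 ± 60.5 to 299 ± 18.6 CPM (SD, n = 5 per group). Between the lines in the Boyden chamber, the death receptor gene Fas was higher with 344SQ by 0.92 ± 0.09, the latent TGF-beta binding protein gene Ltbp2 by 0.61 ± 0.07, and the serine synthesis gene Psat1 was lower (-0.36 ± 0.07). H2-T22, a nonclassical major histocompatibility gene with close paralogs, stood at 113 ± 10.1 CPM with 344SQ and 52.3 ± 4.99 CPM with 393P.

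A hypothesis was that Zeb1 in 344SQ cells sustains part of what sets CAFs with 344SQ apart from CAFs with 393P. It was tested by taking the genes called between the lines in the Boyden chamber to the shRNA table, in a family of 8 fry tests. The 118 genes lower with 344SQ were, on balance, lower with shCTL than with shZEB1 (fry p = 0.0339, adjusted p = 0.0869, median -0.203), as the hypothesis would have it, but the test misses the threshold after adjustment and camera with an estimated correlation gave p = 0.0821. The 253 genes higher with 344SQ decided nothing (fry p = 0.251, adjusted p = 0.291, median 0.278). Planned in advance was the same test with the genes called between the lines in aggregates, and it decided nothing as well. For the 153 genes higher with 344SQ there, fry gave p = 0.821 (adjusted p = 0.821, median 0.117). For the 148 lower genes it gave p = 0.255 (adjusted p = 0.291, median -0.222). The hypothesis may hold for part of the genes called in the Boyden chamber, and the shRNA table is too variable to say more.

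The same family took the genes called between the lines in 1 format to the other, and 2 of these 4 sets passed, both higher with 344SQ on balance. They were the genes called higher in aggregates (median 0.0488 in the Boyden chamber, fry adjusted p = 0.00358) and those called lower in the Boyden chamber (median 0.198 in aggregates, fry adjusted p = 0.00624). Genes called lower in aggregates (median 0.0301) and higher in the Boyden chamber (median 0.138) missed the threshold (fry adjusted p = 0.0869 for both). Camera with an estimated correlation gave p = 0.0487 and 0.00691 for the sets that passed and 0.333 and 0.127 for the others, not adjusted over the 8 tests.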
